A study of Mus musculus with 2 samples.

How the data were processed

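Apoptotic osteoblasts from young and from old mice were compared by RNA sequencing, with 1 library per age group. Per the labels' protocols, bone pieces were cultured, the adherent cells were passaged 3 times to give bone marrow mesenchymal stem cells, and osteogenic medium was given for 3 days to turn these into osteoblasts. Ultraviolet light for 0.5 h then made the cells apoptotic, and over 90% took up Trypan Blue, a dye that enters cells with leaky membranes. RNA was taken up in Trizol and libraries were made with the U-mRNASeq kit. Each library was put in its group by its age label. A treatment label gives day 0 for the young and day 5 for the old library, while the treatment protocol names no treatment, so the meaning of the day was left open.

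The deposited file holds 1 FPKM value (fragments scaled to the gene's length in kilobases and to the library's total) per gene and library for 55487 Ensembl genes, made by the authors. The submitters' processing notes list fastp, STAR, HTSeq, edgeR and the build mm10. The role and version of each tool, the annotation release, any filter and the use of strand are not given in the sources used here. Symbols, positions and transcript lengths came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, which held 55227 of the identifiers. Of all identifiers, 55141 had a symbol.

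The read numbers behind the FPKM values were worked out from the file. Values of low genes lay on steps, and the commonest ratio of low values between the libraries, 0.902 for old over young, was shared by 1038 genes. With the rounded mean length of a gene's annotated transcripts as its length, 97.6% of the values above 0 came out as whole reads within a tolerance of 0.01 (19378 of 19854 in the young library and 20377 of 20884 in the old). The totals were 16333396 reads in the young library and 18114336 in the old. These reads were used for counting intervals, floors, shares of reads and counts of genes with few reads, and no test was run on them. Each 95% interval of a ratio is an exact Clopper-Pearson interval of the old library's share of both libraries' reads, turned into a ratio of FPKM. PCR copies are not independent molecules, so intervals and floors cover counting error only. A gene with no reads was given the value of 3 reads as its upper limit.

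The main measure was the log2 ratio of FPKM + 1, old over young, for the 12561 genes with a mean of at least 1 FPKM over both libraries. Of these, 10964 were protein coding. The pseudocount of 1 makes the ratio smaller for low genes. A gene was counted as higher or lower at 2-fold or more on this scale. With 1 library per group the spread between cultures or animals cannot be estimated, so no test was run and no p-value was made. A comparison of reads would compare these libraries and not the ages.

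Gene lists were fixed before the data were examined. There were 37 lists, 2 of which were families taken by symbol (ribosomal proteins and histones). Of the 687 genes named in lists, 686 had an identifier; for 3 symbols with more than 1 identifier, the identifier with the highest mean FPKM was used. For each list with at least 5 members past the filter, the median log2 ratio was placed among 10000 random lists of the same size, drawn to match mean expression in 20 bins of equal size. The percentile describes where a list lies within these libraries. Lists share some genes and are not independent of each other. A list was called outside the central 95% of random medians when its percentile was above 97.5 or below 2.5.

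The genes named in the text follow a rule that was also fixed beforehand. It takes the 12 highest and the 12 lowest log2 ratios among genes with a mean of at least 10 FPKM, reads in both libraries and a symbol that is not a placeholder or pseudogene name. It adds up to 4 members of each list with the largest differences, a set of bone, clearance, ageing and quality-check genes named in advance, and the 5 most abundant genes of each library. Any other gene is said to have been chosen after its values were seen. Single values of some list members are not reported here.

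Genes that share sequence were marked by cutting each listed gene's transcripts into words of 50 bases, taken every 25 bases, and searching them in the transcripts of all other genes. The overlap of a gene's exons with exons of other genes on either strand was taken from the annotation. Since no source states that strand was used, reads from overlapping genes cannot be told apart.

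The calculation was tested on simulated data for old against young over 12555 genes. Counting noise alone put 21 of 12344 unchanged genes at 2-fold higher and 20 at 2-fold lower. Of planted differences, 0% of 50 genes at 1.5-fold were called, 95.9% of 49 genes at 3-fold, 95.7% of 47 genes at 4-fold and 97.8% of 45 genes at 8-fold. A planted list of 20 genes with a true log2 ratio of 0.50 gave a median of 0.45 and the 100th percentile, and an unchanged list gave a percentile of 70.3.

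The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 10 FPKM, rescaling each library to the same total (TPM), scaling by the median ratio or by the upper quartile, rescaling without the 10 most abundant genes, thresholds of 1.5-fold and 4-fold, 10 bins in place of 20, and random lists drawn without the list's own members. Alternatives chosen after seeing the data were list members with little shared sequence, removal of trends on GC content and transcript length, protein-coding genes alone, genes whose counting interval excludes 2-fold, and the don't-eat-me list without B2m, H2-K1 and H2-D1. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.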

Results

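RNA sequencing measured mRNA in apoptotic osteoblasts, bone-forming cells driven into cell death with ultraviolet light, from young and from old mice. There was 1 library per age group, so no difference has a replicate check, and the labels do not say how many animals or cultures stand behind a library. The young library held 16333396 reads assigned to genes and the old library 18114336, a ratio of 1.11. Reads were found for 19892 genes in the young library and 20925 in the old, and 12531 and 12579 genes reached 1 FPKM. The treatment label reads day 0 for the young and day 5 for the old library, so day and age go together in every comparison. Brackets hold 95% counting intervals of the FPKM ratio, old over young, which cover counting error only. Log2 ratios are of FPKM + 1 and understate the differences of low genes.

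Col1a1, which encodes the main collagen chain of bone, was at 8568 FPKM in the young and 6788 FPKM in the old library and was among the 5 most abundant genes of the young. The others named as most abundant in either library were Gm23935, annotated as a microRNA, at 41279 and 41362 FPKM with its sequence wholly shared with other genes, the ribosomal RNA gene CT010467.1, the translation factor Eef1a1, Rpl41 and the mitochondrial mt-Co1. The 10 most abundant genes took 8.82% of reads in the young and 8.44% in the old library, and mitochondrially encoded genes took 3.29% and 3.43%. Both libraries carried mRNA of the Y-linked genes Ddx3y (14.3 and 11.6 FPKM), Eif2s3y, Kdm5d and Uty, while Xist, the RNA of the inactive X chromosome, had 3 and 11 reads. The median log2 ratio of the 4 measured sex-linked genes was −0.08.

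Markers of blood and vessel cells were scarce in both libraries. Ptprc, the pan-leukocyte marker CD45, had 1 read in the young library and 0 in the old. Of the monocyte and macrophage list, 4 of 25 genes passed the filter with none at 2-fold, among them Lyz2 (21.3 and 18.4 FPKM), Cd74 (8.63 and 7.94) and Cd14 (4.49 and 9.15), and the median log2 ratio was −0.07 against a mean of 0.13. None of the 16 lymphocyte genes passed. Of 13 neutrophil genes the single one to pass was Lcn2, an iron-binding acute-phase protein that other cells also make, at 1.19 FPKM in the young and 13.5 FPKM in the old library (ratio 11.4 [7.03 to 19.5]). The erythroid list had 2 of 12 genes, Tfrc and Epor, with a median of 0.40, and the endothelial list 2 of 15, Flt1 (16.8 and 35.1 FPKM) and Eng, with a median of 0.66. Lists with fewer than 5 measured members were given no percentile.

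The comparison of old with young asks how the mRNA of apoptotic osteoblasts differs with age, in a series concerned with efferocytosis, the engulfment of dead cells by phagocytes. In the old library Cd47, the membrane signal that tells phagocytes not to engulf a cell, was at 295 FPKM against 61.2 FPKM in the young. The eat-me, find-me and bridging signals were also higher as a group, with a median log2 ratio of 0.25. That of the don't-eat-me signals was 0.89. Interferon-response genes, senescence-associated secreted factors and the glycolysis and hypoxia genes were higher in the old library as groups, and Spp1, which encodes the bone matrix protein osteopontin, was higher at 1732 against 224 FPKM. Immediate-early genes, p53 targets and contractile genes were lower as groups, and Txnip, an arrestin-like protein that limits glucose uptake, was lower at 178 against 617 FPKM. Most genes lay close to even, with 11307 of 12561 (90.0%) within 1.5-fold.

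At 2-fold, 248 genes (1.97%) were higher and 109 (0.868%) lower in the old library, so that 69.5% of these genes were higher. The protein-coding ones among them numbered 192 higher and 41 lower, and 65 of the higher and 66 of the lower genes had under 100 reads over both libraries together. The counting interval lay wholly beyond 2-fold for 182 higher and 39 lower genes. At 4-fold, 32 genes were higher and 6 lower. Across genes, which are not independent replicates, Pearson r of the log2 values was 0.978 and Spearman rho 0.979; the median log2 ratio was −0.07 with an SD of 0.40. The counts depend on how low genes are treated, with 408 higher and 236 lower at a pseudocount of 0.1, 101 and 20 at a pseudocount of 5, and 106 and 27 at a mean of at least 10 FPKM. Rescaled without the 10 most abundant genes, 365 were higher and 192 lower, a step that also raises all values against the fixed filter and pseudocount. Of 62 named genes at 2-fold, 10 were under it at a pseudocount of 5, namely Slc2a1 (0.999), Mmp13 (−0.90), Flt1 (0.88), Dmp1 (0.87), Cxcl5 (0.79), Il34 (0.73), Ccn2 (−0.72), Car9 (0.70), C4b (0.45) and Hist2h2aa2 (0.40).

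**Figure D1:**
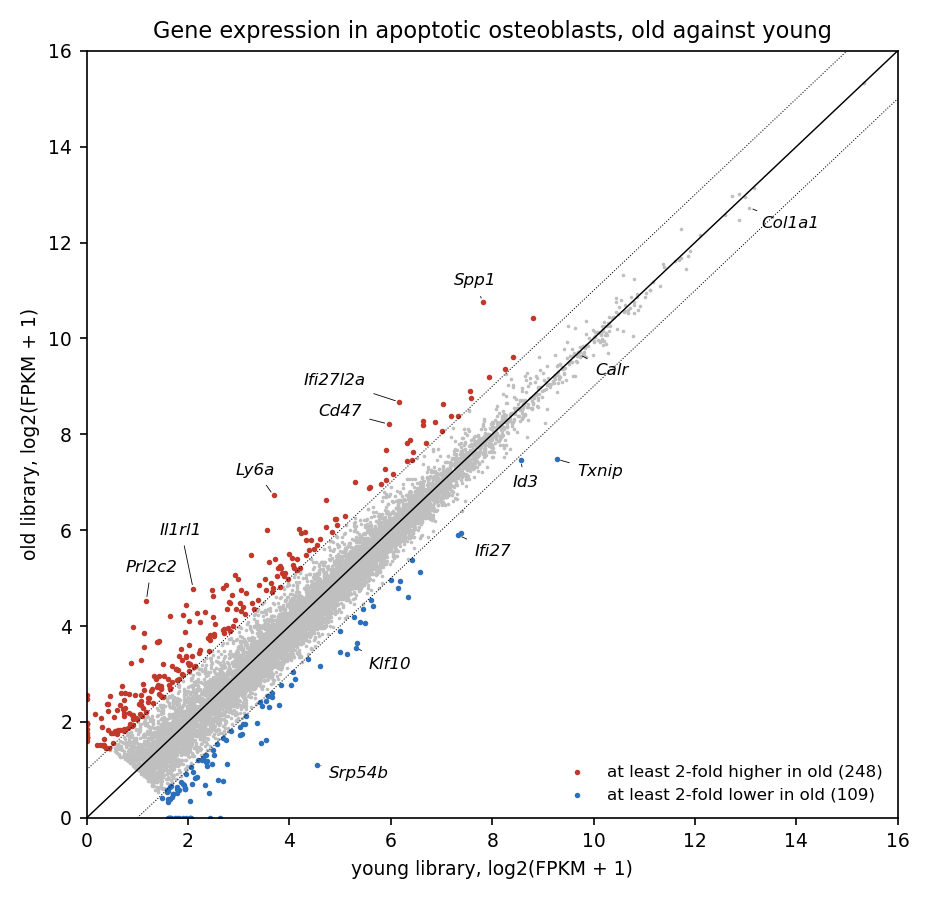
Expression of the 12561 tested genes, as log2(FPKM + 1), in the young library (horizontal axis) and the old library (vertical axis); each point is a gene, the solid line marks equal values and the dotted lines 2-fold. Of the coloured points, 248 genes lie above the upper dotted line and 109 below the lower, with Cd47 and Spp1 among the former and Txnip and Klf10 among the latter.

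The genes with the highest and lowest ratios among those with a mean of at least 10 FPKM are described singly, without a test for a shared function. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, GRCm38), the stem cell antigen Sca-1, was at 11.9 FPKM in the young and 105 in the old library, a ratio of 8.82 [7.46 to 10.5], with 10.6% of its words shared with other genes. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) rested on 3885 and 33348 reads, a ratio of 7.74 [7.49 to 8.0], with 18.8% of its exon bases overlapped by another gene. Il1rl1, the receptor for interleukin-33, was at 3.29 and 26.5 FPKM, a log2 ratio of 2.68. Ifi27l2a, an interferon-inducible gene, was at 70.9 and 407 FPKM, Tnfrsf9, the receptor 4-1BB, at 2.91 and 20.8 FPKM, the matricellular gene Ccn5 at 10.8 and 63.5 FPKM, and the acute-phase gene Saa3 at 2.71 and 17.8 FPKM. Cd47, described with the clearance signals, was also among the 12 highest. The values of Prl2c2 (88.9% of its words shared), Ass1 (44.4%), Ly6c1 (38.6%) and P3h2 (23%) are uncertain, with log2 ratios of 3.35, 2.15, 2.28 and 2.25.

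Among the lowest ratios, Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883) had 12990 and 4147 reads, a ratio of 0.288 [0.278 to 0.298], with 19.4% of its exon bases overlapped. Its relative Arrdc4 was at 39.2 FPKM in the young and 11.5 in the old library, and Klf10, a TGF-beta-inducible repressor, at 38.5 and 10.7 FPKM. Fgfr3, a fibroblast growth factor receptor that restrains bone growth, was at 31.1 and 9.97 FPKM, and Btg2, an antiproliferative p53 target, at 69.4 and 26.8 FPKM. Ifi27 had a ratio of 0.368 [0.338 to 0.401], opposite in direction to its neighbour Ifi27l2a. The long RNA Dnm3os, with a log2 ratio of −1.30, and Ttll3, with −1.44, were also lower. Mir143 (35 and 11 reads) and Mir145a (50 and 20 reads) lie next to each other on chromosome 18 and rest on few reads. Srp54b (log2 ratio −3.44, 90.5% of its words shared) and Sarnp (−1.43, 53.1% shared) are uncertain.

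Among the listed signals by which dying cells invite or refuse engulfment, the mRNA of Cd47 differed most. Protein at the cell surface was not measured. Cd47 (ENSMUSG00000055447, chromosome 16, 49800533 to 49915010) had 1694 reads in the young and 9066 in the old library, a ratio of 4.83 [4.58 to 5.09], and it ranked 20 of 12561 genes by log2 ratio and 3 of the 1160 genes with a mean of at least 100 FPKM. Of the 7 measured don't-eat-me genes, 3 were at least 2-fold higher and none lower, with a median of 0.89 above all 10000 random lists. H2-K1 (188 and 478 FPKM) and H2-D1 (305 and 661 FPKM), classical class I genes, followed Cd47. The median was 0.44 with no filter and 0.36 over the 4 members left without the class I genes B2m, H2-K1 and H2-D1.

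Eat-me, find-me and bridging signals had a median of 0.25 at the 99.99th percentile, with 2 of 18 genes at least 2-fold higher and none lower. These were Lgals3, the bridging lectin galectin-3, at 98.3 and 309 FPKM (ratio 3.14 [2.96 to 3.34]), and Lrp1 at 337 and 786 FPKM. As the receptor for calreticulin, Lrp1 is not itself such a signal, though the list fixed beforehand held it. The chemokine Cx3cl1 (79.3 and 134 FPKM) and annexin Anxa1 (487 and 785 FPKM) had log2 ratios of 0.75 and 0.69. Calr, which encodes the eat-me protein calreticulin, was close to even at 829.9 and 815 FPKM, a ratio of 0.982 [0.961 to 1.0]. In the phagocyte receptor and engulfment list, 1 of 13 genes was 2-fold higher and none lower, and the median of 0.20 lay at percentile 99.3. The TAM receptors differed in direction, with Axl at 58.4 and 155 FPKM and Mertk at 7.87 and 4.25 FPKM, while the integrins Itgb3 and Itgb5 had log2 ratios of 0.51 and 0.44. That call ended at a pseudocount of 5 (median 0.09, percentile 95.2) and at a mean of at least 10 FPKM (0.12, percentile 94.95).

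**Figure D2:**
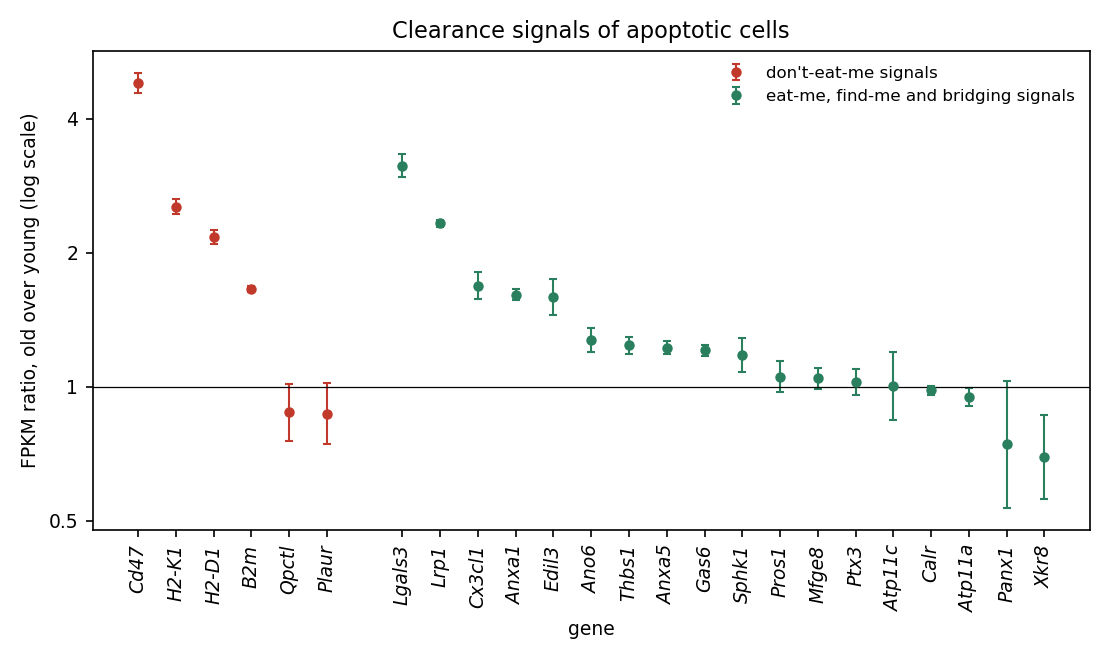
Ratio of FPKM, old over young, on a log axis, for 6 of the 7 measured don't-eat-me genes (red) and the eat-me, find-me and bridging genes (green); points are ratios of 1 library to 1 library and bars are 95% counting intervals, which hold no spread between cultures. Cd47 lies highest at 4.83, Lgals3 is the highest green point at 3.14, and Calr lies at 0.982.

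Among the lists with a percentile, the interferon-response genes had the median farthest from 0. All 28 measured members had log2 ratios above 0, 16 were at least 2-fold higher in the old library, and the median of 1.19 lay above all 10000 random lists, whose central range was −0.18 to 0.05. The largest differences were those of Zbp1, a sensor of Z-form nucleic acid (0.88 and 14.9 FPKM, ratio 17.0 [11.7 to 25.6]), Mx1, an antiviral GTPase (1.11 and 8.85 FPKM), and Oas2, an enzyme of the RNase L pathway (6.88 and 30.6 FPKM). Oas1a, of the same family, had a log2 ratio of 1.95, with 58.1% of its words shared.

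Senescence-associated secreted factors were higher as a group, with 8 of the 18 measured genes (of 32 listed) at least 2-fold higher and 1 lower, and a median of 0.97 above all random lists. The chemokines Ccl7 (6.57 and 32.5 FPKM), Ccl5 (5.41 and 26.6 FPKM), Ccl2 (12.1 and 41.2 FPKM) and Cxcl5 (0.32 and 4.17 FPKM, on 9 and 130 reads) led it, and the lower gene was the collagenase Mmp13. The median was 0.49 at a pseudocount of 5 and 0.41 with no filter, above all random lists in both. The list of cell-cycle inhibitors and senescence markers had no gene at 2-fold among 11, a median of −0.19 and percentile 3.97. In it Cdkn1a, the p21 inhibitor, was at 382 and 346 FPKM, Cdkn1b had a log2 ratio of −0.21, and the chromatin genes Hmgb2 (179 and 120 FPKM), Hmgb1 and Bmi1 had −0.57, −0.35 and −0.31. That list lay below the central range with no filter (percentile 2.46) and after removal of GC content and length trends (percentile 1.81). Cdkn2a, the p16 and p19ARF gene, had 0 reads in both libraries, which allows up to 0.210 FPKM in the young and 0.189 FPKM in the old; its neighbours Mtap and Cdkn2b, chosen after their values were seen, also had 0.

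The immediate-early list had a median of −0.43, below all 10000 random lists, with 1 of 23 genes at least 2-fold higher and none 2-fold lower. Ier2 (176 and 95.9 FPKM), the zinc finger factor Egr1 (112 and 61.9 FPKM) and Atf3 (3.50 and 1.62 FPKM) were lower, whereas the AP-1 member Fosl1 was at 5.68 and 28.0 FPKM with 57.2% of its exon bases overlapped by other genes. The median was −0.28 at a pseudocount of 5 and −0.18 at a mean of at least 10 FPKM. The p53 targets had a median of −0.25 at percentile 0.06 with 1 of 24 genes 2-fold lower and none higher; after Btg2 the largest differences were in Rrm2b (10.7 and 5.41 FPKM), Trp53inp1 (67.6 and 43.1 FPKM) and Sesn2 (43.6 and 28.1 FPKM). Apoptosis regulators lay inside the central range, with no gene of 26 at 2-fold, a median of −0.12 and percentile 20.4. Their largest differences were in Diablo (log2 ratio −0.99, 56.0% of words shared), the BH3-only genes Bcl2l11 (19.8 and 11.96 FPKM) and Bad (−0.48), and the inhibitor Birc2 (−0.48). The unfolded protein response had no gene of 21 at 2-fold and a median of −0.12 at percentile 15.3, with Trib3, Chac1, Ern1 and Ppp1r15a between −0.48 and −0.34. Heat shock genes had none of 15 at 2-fold and a median of 0.08 at percentile 95.4, with Cryab, Bag3 and Hspd1 at 0.42, 0.38 and 0.34 and Hspa1b (61.3% of words shared) at 0.77.

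Glycolysis and hypoxia genes were higher as a group, with 21 of 22 log2 ratios above 0, 2 genes at least 2-fold higher (neither of them at a pseudocount of 5), none lower, and a median of 0.59 above all random lists. The pH regulator Car9 (1.65 and 5.81 FPKM), the glucose transporter Slc2a1 (21.4 and 47.7 FPKM) and hexokinase Hk2 (6.93 and 14.7 FPKM) differed most, followed by Pgk1 at 0.90 with 62.7% of its words shared. Antioxidant and NRF2 targets had 3 of 23 genes at least 2-fold higher, none lower, and a median of 0.21 above all random lists, or 0.11 at percentile 99.3 with a mean of at least 10 FPKM. The glutathione transferase Gsta4 was at 2.85 and 13.7 FPKM, the extracellular superoxide dismutase Sod3 at 11.5 and 28.7 FPKM, the quinone reductase Nqo1 at 33.4 and 77.2 FPKM and the metallothionein Mt2 (73.5% overlapped) at 120.3 and 206 FPKM. Nuclear-encoded oxidative phosphorylation had none of 28 genes at 2-fold and a median of −0.09 at percentile 14.1, with Ndufb5, Ndufa1, Ndufs1 and Ndufs3 between −0.43 and −0.30. Mitochondrially encoded genes had a median of 0.06 at percentile 88.2, or 0.24 at percentile 99.2 after removal of GC content and length trends. The single one of 12 at 2-fold was mt-Atp6, whose sequence is wholly shared with other genes; mt-Nd6 had 0.50, mt-Nd5 −0.27 and mt-Nd4l −0.33. Autophagy and lysosome genes had none of 28 at 2-fold and a median of 0.02 at percentile 86.1, with Npc2 and Grn at 0.46 and 0.41 and Map1lc3a and Atg12 at −0.46 and −0.39.

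Genes of the osteoblast lineage went both ways. Spp1 and Dmp1, matrix proteins of mineralising bone, were 2 of the 16 measured genes and the only ones at 2-fold, both higher, with Dmp1 at 0.38 and 4.85 FPKM (ratio 12.9 [7.88 to 22.5]) and a log2 ratio of 2.09, or 0.87 at a pseudocount of 5. The pyrophosphate transporter Ank was at 27.0 and 46.9 FPKM. The lineage transcription factors Sp7 (55.5 and 28.9 FPKM, ratio 0.521 [0.482 to 0.562]) and Runx2 (92.1 and 72.7 FPKM, ratio 0.789 [0.751 to 0.829]) were lower, as was Col1a1 (ratio 0.792 [0.788 to 0.797]). Alpl, the alkaline phosphatase of bone, was low in both at 2.78 and 3.28 FPKM, a ratio of 1.18 [0.746 to 1.87], and Bglap, osteocalcin, had 3 and 6 reads. The list median was −0.13 against a mean of 0.19, at percentile 10.2; it was −0.34 at percentile 0.01 with a mean of at least 10 FPKM, −0.22 at percentile 1.83 over the 12 members with little shared sequence, and 0.03 with no filter.

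Marrow stromal genes had a median of 0.49 above all random lists, with 2 of 15 at least 2-fold higher and none lower. After Ly6a came the BMP antagonist Grem1 (1.67 and 11.7 FPKM), the hedgehog target Gli1 (4.56 and 10.1 FPKM, just under 2-fold on the log2 scale) and the chemokine Cxcl12 (113 and 201 FPKM). Of the adipocyte list 6 of 18 genes passed the filter, and Pparg, Adipoq, Fabp4 and Plin1, chosen after their values were seen, had at most 8 reads in a library. The measured genes had a median of 0.34 at percentile 99.5, with 1 at least 2-fold higher, none lower, and medians of 0.22 at a pseudocount of 5 and 0.17 with no filter. The higher gene was the transcription factor Cebpb (84.7 and 177 FPKM), followed by Scd1 (0.70), Fabp5 (0.37) and Cebpa (0.30). Chondrocyte genes had none of 6 at 2-fold and a median of −0.04 at percentile 53.3, with Sox5 at 0.80, Sox6 at −0.68, Comp at −0.23 and Col2a1 at −0.18. Contractile and myofibroblast genes had 1 of 13 at 2-fold lower, none higher, and a median of −0.26 at percentile 0.25. They included Ccn2 (11.5 and 5.06 FPKM), Ankrd1 (15.3 and 8.81 FPKM), tropomyosin Tpm1 (1253 and 829.7 FPKM) and Ccn1 (358 and 264 FPKM).

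Fibrillar matrix genes had none of 22 at 2-fold in either direction, and their median of 0.24 lay above all random lists. Examples were the collagen cross-linking enzymes Loxl1 (9.47 and 17.9 FPKM) and Lox (61.9 and 107 FPKM), Col6a2 (315 and 522 FPKM) and Fbln2 (152 and 231 FPKM). Matrix proteases and their inhibitors went both ways, with 3 of 16 genes at least 2-fold higher and 1 lower, a median of −0.01 against a mean of 0.19, and percentile 71.3, or a median of 0.13 at percentile 99.1 with a mean of at least 10 FPKM. The inhibitors Timp3 (98.2 and 290.2 FPKM) and Timp1 (65.2 and 143 FPKM) and the protease Mmp19 (10.5 and 30.7 FPKM) were higher, and Mmp13 (15.3 and 5.84 FPKM) was lower.

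Osteoclast regulators made by osteoblasts had a median of 0.31 at percentile 99.8, with 1 of 10 genes at least 2-fold higher and none lower. The macrophage growth factor Il34 (2.51 and 7.45 FPKM), the prostaglandin synthase Ptgs2 (9.21 and 18.8 FPKM) and osteoprotegerin, Tnfrsf11b (3.76 and 6.09 FPKM), were higher, and Lgr4 had −0.55. That call ended with a mean of at least 10 FPKM (0.16 over 6 members, percentile 95.6), and the median was 0.18 at a pseudocount of 5. Osteoclast genes had none of 6 at 2-fold and a median of 0.12 at percentile 92.1, with Mmp9 at 0.80, Itgb3 at 0.51, Nfatc1 at 0.13 and Ctsk at −0.11. Complement genes had 2 of 6 at least 2-fold higher, C3 (145 and 330.1 FPKM) and C4b (log2 ratio 1.08, or 0.45 at a pseudocount of 5, with 33.6% of its words shared), none lower, and a median of 0.02 at percentile 67.7, with Cfp at −0.98.

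Wnt pathway genes had a median of 0.07 at percentile 89.7. The agonist Rspo2 (4.66 and 17.4 FPKM) was the single one of 12 at 2-fold, while Wnt10b (34.3 and 17.5 FPKM), Wif1 and the feedback target Axin2 had log2 ratios of −0.93, −0.57 and −0.47. TGF-beta and BMP genes had a median of 0.04 at percentile 95.6, with 1 of 23 at least 2-fold higher, the antagonist Grem1, and 2 lower. The lower ones were the BMP targets Id2 (49.3 and 20.5 FPKM) and Id3 (376 and 176 FPKM), and the ligand Bmp4 was at 53.7 and 26.6 FPKM. The TGF-beta and BMP list lay above the central range under 4 alternatives, at percentile 97.75 with no filter, 97.76 rescaled to TPM, 98.2 scaled by the median ratio and 98.3 without the 10 most abundant genes. Cell-cycle genes had none of 34 at 2-fold and a median of −0.10 against a mean of 0.00, at percentile 16.5. Within them the replication genes Mcm7, Mcm6, Tk1 and Mcm2 had log2 ratios between 0.40 and 0.45, while Mki67, the Ki-67 marker of dividing cells, was at 94.1 and 79.3 FPKM.

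Of the gene families, ribosomal proteins had none of 97 at 2-fold and a median of −0.01 at percentile 63.1; the rule by symbol also took in 14 like-named genes such as Rps6kb2 (−0.41). The largest differences were in Rps27a (0.98), Rpl17 (−0.50) and Rpl30 (0.46), sharing 46.0%, 56.1% and 37.8% of their words with other genes. Over 20% of words were also shared in Hmgb1, Hmgb2, Bmi1, Mcm7, Hspd1, Ndufs3, Bglap, Eef1a1, Rpl41, mt-Co1, mt-Nd4l, CT010467.1, Hist1h3i and Hist1h4i, and over 20% of exon bases were overlapped in Cebpb, Ccn2, Timp3, Mmp19, Bad, Rps6kb2 and CT010467.1, so these values are less certain. Histones had 2 of 20 at least 2-fold higher, none lower, and a median of −0.04 against a mean of 0.05 at percentile 51.6. Both higher ones, Hist1h2ao and Hist2h2aa2, share nearly all of their sequence with other genes; Hist1h4i had 0.61 and Hist1h3i, on 11 and 4 reads, −0.78. In all, 11 of the 31 lists with a percentile lay above and 3 below the central 95% of random lists. How many would do so between 2 cultures of 1 age is not known, because genes of a list vary together and lists share members.

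**Figure D3:**
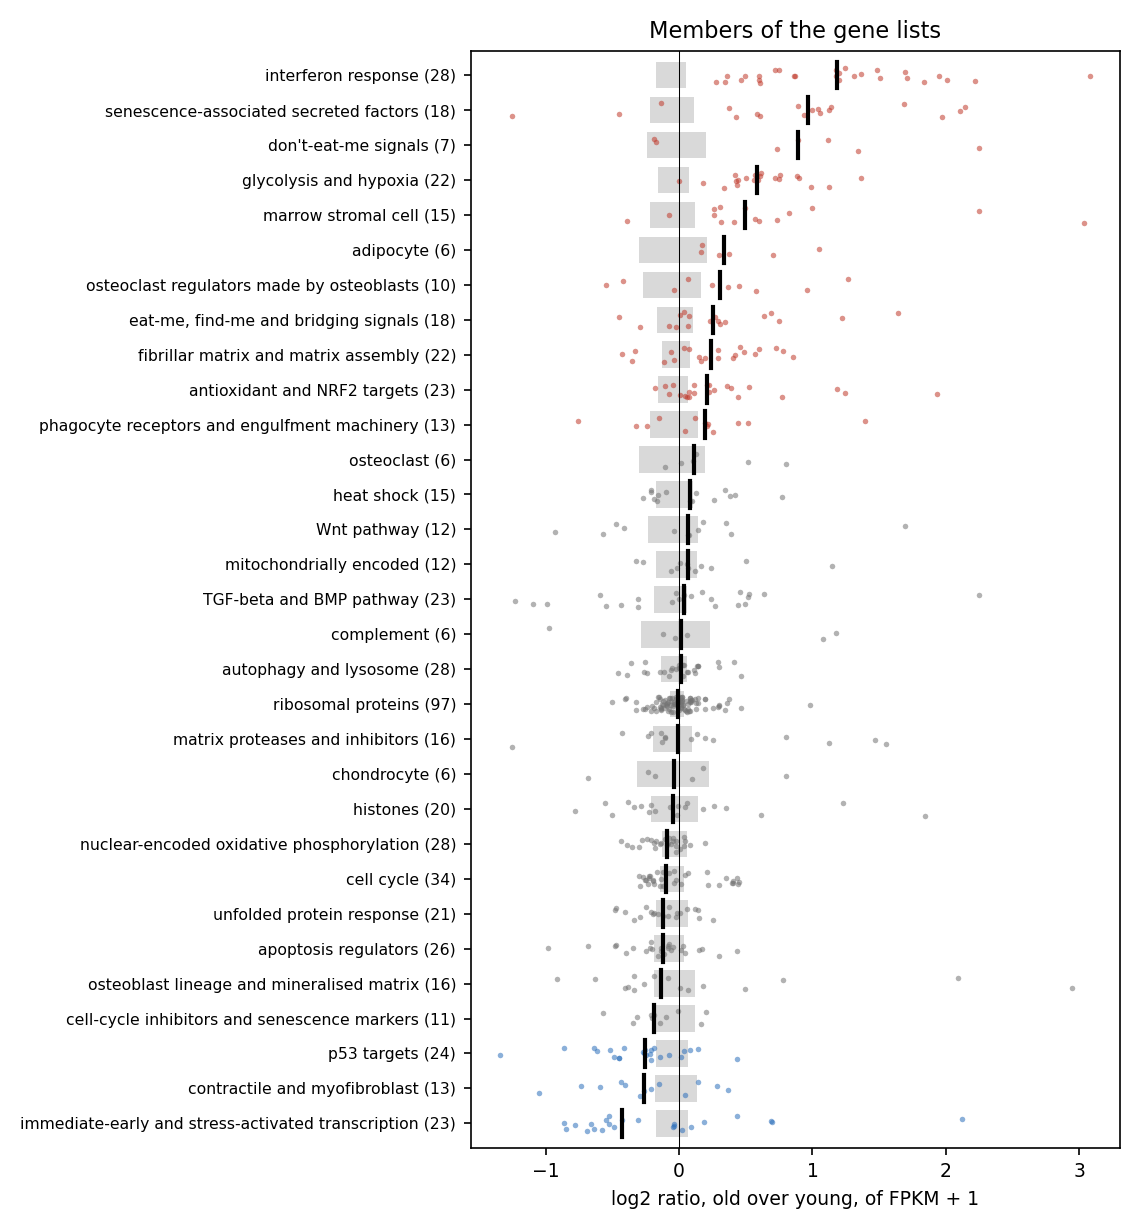
Log2 ratio of FPKM + 1, old over young, of the measured members (points, number in brackets) of each list with a percentile; black bars are medians and grey boxes the central 95% of the medians of 10000 random lists matched on expression. Red lists lie above and blue lists below their box, and the interferon list has the highest median at 1.19 and the immediate-early list the lowest at −0.43.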

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

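The alternatives on shared sequence, GC content and length, protein-coding genes, counting intervals and the reduced don't-eat-me list were chosen after seeing the data; the others were fixed beforehand. Of 62 named genes at 2-fold or more, all 545 values under alternatives kept their direction, and 10 genes were under 2-fold in 1 or more of them, 9 at a pseudocount of 5 alone and Ccn2 also with median-ratio scaling (−0.99). The 14 called lists kept their direction in 138 of 138 values and stayed outside the central range in 134 of 137 with a percentile; the exceptions were the phagocyte receptors (2 values) and the osteoclast regulators (1 value), given with those lists. A pseudocount of 0.1 gave 408 higher and 236 lower genes, r of 0.967 and a median of 1.08 for the secreted factors. A pseudocount of 5 gave 101 and 20 genes, with medians of 0.74 for don't-eat-me signals, 0.49 for secreted factors and 0.84 for interferon genes. Both follow from its construction, as a larger pseudocount shrinks the ratios of low genes. With no filter r was 0.990, and the medians were 0.025 for the osteoblast lineage, 0.44 for don't-eat-me signals and 0.41 for secreted factors. A mean of at least 10 FPKM gave 106 and 27 genes from 8264 tested, r of 0.970 and −0.34 for the osteoblast lineage. Median-ratio scaling gave 0.32 for eat-me signals, 1.25 for interferon genes and 0.66 for glycolysis and put 76.3% of the 2-fold genes higher, against 69.5%; it lifts every gene alike. Rescaling without the 10 most abundant genes gave 365 higher and 192 lower of 13390 tested, with 65.5% higher. This rescaling raises all values above the deposited scale (totals of 735012 FPKM in the young and 732517 in the old library). The fixed filter and pseudocount then weigh less, which by construction adds low genes to both counts. Rescaling to TPM, which raises values less, gave 313 and 160 of 13090. Any effect of the abundant genes themselves was not tested. Thresholds of 1.5-fold and 4-fold gave 693 and 561, and 32 and 6 genes. The osteoblast lineage had −0.22 over members with little shared sequence, for a cause that was not tested. Interferon genes had 1.26 after removal of GC content and length trends. By construction this removal also takes out the median log2 ratio of all genes, −0.07, and median-ratio scaling without it gave 1.25. Protein-coding genes alone gave 41 lower, and a counting interval beyond 2-fold left 39 lower. Don't-eat-me signals without B2m, H2-K1 and H2-D1 had 0.36 over 4 members. The share of 2-fold genes that were higher was 83.5% at a pseudocount of 5 and 82.4% for protein-coding genes. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth limits low genes most, since 3 reads stand for 0.109 FPKM of Mtap in the young and 0.0987 FPKM in the old library.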

Other observations

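The gene groups in the first paragraphs, the tests on immune cells and on the recorded day, and the removal of GC content and length trends were chosen after the results were seen. Of 10 interferon-inducible membrane and Ly6 protein genes, 8 were at least 2-fold higher in the old library and 1 lower, with a median of 1.57; 2 of the 10 are also in lists fixed beforehand. Ifitm3, which blocks virus entry, was at 446 and 1373 FPKM in the young and old library, Ifitm1 at 18.8 and 61.5 FPKM and Ly6e at 81.8 and 235 FPKM, beside Ly6a and Ifi27l2a. The exception was Ifi27, with a log2 ratio of −1.43. Genes of class I antigen presentation had 5 of 21 at least 2-fold higher, none lower and a median of 0.36, with 7 of the 21 in lists fixed beforehand. Both sets were put together around genes already seen to be higher, so neither is independent evidence. The class I transactivator Nlrc5 was at 4.73 and 12.8 FPKM, H2-T23 at 13.1 and 27.2 FPKM, B2m at 1533 and 2545 FPKM and the immunoproteasome subunit Psmb9 at 14.02 and 22.2 FPKM.

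Txnip, Arrdc4 and Klf10, which respond to glucose through the factor MondoA and its partner, were among the 12 lowest named genes, which have a mean of at least 10 FPKM, with log2 ratios of −1.79, −1.68 and −1.76. The transcripts of the factors themselves were close to even, with Mlxip, which encodes MondoA, at 16.8 and 17.6 FPKM and Mlx at 40.1 and 36.8 FPKM. The set of 5 was put together because its targets stood out, so its median of −1.68 is no independent evidence.

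As an explanation of the higher interferon-response genes, immune cells in the old library are argued against for macrophages by the monocyte and macrophage list, whose summed FPKM was 40.9 in the young and 42.7 in the old library, a ratio of 1.04; its most abundant gene, Lyz2, was at 21.3 and 18.4 FPKM. The neutrophil list summed to 1.35 and 14.4 FPKM, of which Lcn2 made 1.19 and 13.5 while the abundant neutrophil genes S100a8 and S100a9, chosen after their values were seen, had at most 1 read in a library, and the lymphocyte list summed to 0.627 and 0.901 FPKM. After the trends of all tested genes on GC content and transcript length were removed, the median was 1.26. With 90.0% of tested genes within 1.5-fold, these trends left little to remove. The correction could therefore hardly have lowered the median, and it does not decide whether such a bias had a part. It shows only that trends across all tested genes were small beside the difference of this list. A bias limited to few genes is not touched by it. The day recorded with the age label cannot be told apart from age, because 0 libraries cross day and age. A difference with age, or between single cultures, may account for the pattern and stays untested.

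No reads were assigned to Mtap, Cdkn2a or Cdkn2b in either library, nor to any of the 7 genes annotated between 89137122 and 89311039 on chromosome 4 (GRCm38), while Gm12602, 8896 bp to the left, had 87 and 133 reads. Reads lost to overlapping or near-identical genes are argued against, as 0% of Mtap's exon bases were overlapped and 0 of its 131 words were shared. A methionine salvage pathway not transcribed as a whole is argued against too, since 0 of the 4 other pathway genes (Mri1, Apip, Enoph1 and Adi1, between 19.1 and 58.4 FPKM) were under 1 FPKM in both libraries. A shared loss of the chromosomal interval, in the cultures or their source animals, is a candidate explanation: 0 genes of the interval had a read. Among the 7, only Mtap, Cdkn2a and Cdkn2b code for protein, and the interval was drawn from Mtap to Cdkn2b after their values were seen. The others are processed pseudogenes, a small nucleolar RNA and a long noncoding RNA, so their lack of reads adds little. Silence of the interval would look the same, since 7048 of 21974 protein-coding genes (32.1%) were at 0 in both libraries, the next gene with 10 or more reads on the right lay 2.49 Mb away, and no DNA was measured. That share is over all protein-coding genes and is not the rate for a gene like Mtap, whose 4 pathway partners were transcribed.

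The higher glycolysis and hypoxia genes could reflect oxygen-sensing (HIF) transcription. HIF targets outside that list had a median log2 ratio of 0.078 over 17 genes at percentile 97.75, with 12 above 0 and 5 below. Examples, chosen after their values were seen, were Ak4 (3.67 and 7.64 FPKM) and Plod2 (65.5 and 59.5 FPKM). The median is short of the 0.30 set beforehand for this explanation, yet just outside the range set against it, so the explanation stays open. After the trends on GC content and transcript length were removed, the median was 0.64. As for the interferon genes, the correction could hardly have lowered the median. It therefore does not decide on a bias shared by all genes, nor on a bias limited to few genes. Age and the recorded day stay open as well and were not tested.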
